A study of Mus musculus with 2 samples.

How the data were processed

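H3K36me3 ChIP-seq peak lists of 2 biological replicates of embryonic day 16.5 mouse forebrain were analysed: 1 list per replicate, 1 called on the reads of both replicates together (the pooled list) and 1 of replicated peaks that the authors derived from the other 3, per the file descriptions. The labels give mm10 as the assembly. The aligner, the peak caller and its threshold are not given in the sources used here. Per the deposited descriptions, the list of replicate 1 was made from its alignments and a pair of further files that are not described, and the list of replicate 2 from its alignments and only the first of that pair. Whether the processing differed or the description is incomplete is not known. Control libraries were not analysed here.

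Each deposited peak has a score scaled by the authors to the strongest peaks of its list, which was not used further. The authors' signal value per peak is taken as a linear ratio from the file format and its values, since the caller is not named. It is here called fold and was used to rank or filter peaks within a list and, in 1 test of the X chromosome, to compare peaks above different limits. The deposited −log10 p and −log10 q values are those of the authors' peak caller. The lists stop near a −log10 p of 2 (lowest values 2.02 and 2.01) and were not limited on q: 63.9% of replicate 1 peaks and 11.9% of replicate 2 peaks had a −log10 q of at least 2. All 79870 replicated peaks are peaks of the pooled list with unchanged values. All 42355 pooled peaks that overlap both replicates' own lists over 50% of either peak are in the replicated list, and so are 37509 that do not meet that rule, so the authors' rule was another one. Read counts are not in these lists and the depth per sample is unknown. No interval that needs read counts is given, and a gene without a peak may still carry the mark below the calling limit.

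Peaks were set against GENCODE M21 gene models, whose build (GRCm38) is mm10. No peak reached past a chromosome end. Gene results used the 21 assembled chromosomes and left out 12 and 7 peaks on unplaced scaffolds. The covered share of a gene is the percentage of its annotated span inside merged peaks, and a gene was marked with at least 10% in each replicate's own list. Bases that lie in several genes count for each of them. Position along the gene used 10 equal bins in protein-coding genes of at least 5 kb that overlap no other coding gene. Exon bases are those in any annotated exon of a protein-coding gene and intron bases the rest of the span. Peaks were called shared when they overlapped over at least 50% of either peak. Overlaps were set against 100 circular shifts of the peaks within each chromosome, and an overlap beyond the highest shift was taken as past the threshold.

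The 30 gene lists, the comparisons, the alternatives and the rules for naming genes were fixed before the data were examined, apart from those that the text gives as added or chosen after the data were seen. For each list, the median covered share was ranked among 10000 random lists of protein-coding genes of the same size drawn from the same 20 bins of gene length, in each replicate. A list stood above, or below, when it lay above, or below, the middle 95% of random lists in both replicates. Named genes were drawn from the 3 highest and 2 lowest members of each list (not all of which are named), the 10 genes of highest covered share among marked genes of at least 5 kb, the 10 with the most covered bases, the 5 replicated peaks of highest fold and the 5 longest, the 5 genes of at least 5 kb that differ most between replicates in each direction, and Setd2 and Nsd1. Members tied at 0 were ranked by symbol. Cell type lists covered pan-neuronal, pallial, subpallial, radial glia, astrocyte, oligodendrocyte, microglia, endothelial, meningeal, choroid plexus and erythroid genes. With 1 group of 2 replicates there was no test between groups, and values are given as mean ± SD (n = 2) without p-values across genes or peaks in the comparisons. The closing section has 2 permutation tests across genes, which treat genes as units although genes are not independent replicates.

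The scripts were tested on simulated data. Of 200 random lists of 16 genes 1.5% were called above and 0% below, and of 200 lists with 8 marked genes 96.5% were called above. Lists of 16 genes with no covered base were called below in 0% of cases, so the rule on medians could not call such lists below. A planted position ratio of 3 was recovered as 2.97, and 4 overlap counts equalled those of bedtools. Alternatives were other peak thresholds (−log10 q of at least 5 or, added later, 2; fold of at least 3), peaks joined within 1 kb, equal peak numbers, the authors' pooled and replicated lists, each replicate alone, other overlap, length and coverage limits, other gene sets and other list measures. Removal of read-through gene models, the mean covered share of lists and a count of bases inside a single coding gene only, with read-through models left out, were also added later. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and bedtools 2.31.1 served as a check of overlaps.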

Results

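Trimethylation of histone H3 at lysine 36 (H3K36me3), a modification laid down along transcribed gene bodies, was mapped by ChIP-seq in the forebrain of mouse embryos at day 16.5 of gestation. In this assay, DNA fragments bound to the modified histone are pulled down with an antibody and sequenced, and regions with more fragments than background are reported as peaks. The embryos were of strain B6NCrl, males and females were pooled, and the single group held 2 biological replicates, the second of them a pool of 41 embryos. The deposited lists held 118349 peaks for replicate 1 and 75032 peaks for replicate 2. They covered 37.4 Mb and 23.2 Mb, or 1.37% and 0.849% of the assembled mm10 chromosomes, with a median peak width of 248 bp and 247 bp. Read numbers are not in the lists, so the sequencing depth behind them is unknown. With no other tissue, stage or treatment in the series, the design asks which genes and which parts of genes carried the mark, and how alike the replicates were. A gene was called marked when at least 10% of its span lay inside peaks in each replicate's own list, and values are the mean ± SD of the replicates (n = 2).

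Many genes of the general cell machinery carried the mark in this tissue, some pan-neuronal genes did, and markers of vessels, meninges, blood and other organs mostly held no peak. Among the splicing factor genes, 21 of 23 were marked, led by Prpf8, a core spliceosome protein, with 53.8% ± 6.13 (SD, n = 2) of its span inside peaks, Snrpa with 47.5% ± 3.59 and the RNA helicase gene Snrnp200 with 47.0% ± 5.65. Of the proteasome genes 24 of 39 were marked, with Psma1 at 40.6% ± 14.5, Psmc1 at 39.1% ± 9.59 and Psmb6 at 36.1% ± 0.568 highest, while Psmb8 and Psmb9, which encode immunoproteasome subunits, held no covered base in either replicate. The pan-neuronal list had 5 of 16 genes marked, the highest being Stmn1, a regulator of microtubule turnover, at 30.6% ± 3.16, the neurofilament gene Ina at 21.8% ± 3.07 and the neuronal tubulin gene Tubb3 at 19.3% ± 4.79. None of the 12 endothelial and pericyte genes, 12 meningeal and mesenchymal genes, 12 erythroid genes, 14 liver genes or 39 Hox genes was marked, but most genes were not: 13.1% of all protein-coding genes were marked and 53.7% held no covered base. By the share of marked members only the Hox list of these 5 lay below length-matched random lists, and the erythroid list lay within them by every measure used.

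Against 10000 random gene lists of the same size and gene length, 9 of the 30 preset lists had a median covered share above the middle 95% of the random lists in both replicates. The splicing factor genes had the highest medians, 37.9% in replicate 1 and 21.9% in replicate 2, followed by the proteasome genes with 21.8% and 16.5%. The cytosolic ribosomal protein genes had 36 of 80 members marked, with medians of 15.7% and 9.41% and Rpl23 (38.3% ± 3.92), Rpl14 (37.9% ± 2.36) and Rpl13a (36.5% ± 8.87) highest, although 79.1% of the covered bases of Rpl13a lay in the overlapping model Gm45713. Rps27 and Rps21 in the same list held no covered base. The mitochondrial respiratory chain genes had 25 of 75 members marked, with medians of 9.15% and 6.27%, with the ATP synthase subunit genes Atp5b (43.6% ± 8.10) and Atp5a1 (40.7% ± 9.30) and the complex III gene Uqcrb (41.3% ± 4.34) highest. The 365 zinc finger genes named Zfp and a number had 158 members marked and medians of 13.8% and 7.58%. Of the clustered protocadherin genes, which encode adhesion molecules of neurons, 17 of 56 were marked, with medians of 3.68% and 3.01%, but these genes overlap one another and 16 of the 17 had all of their covered bases inside other coding genes. With only bases inside a single coding gene counted, a measure added after the data were seen, their medians were 0 and the list lay within the random range, while the other 8 lists stayed above it. The housekeeping list had 6 of 14 genes marked, with Tubb5 at 55.0% ± 11.4, Tbp at 33.4% ± 9.96 (19.6% of its covered bases shared with Pdcd2) and Polr2a, the largest subunit of RNA polymerase II, at 29.7% ± 11.9, and with Hmbs and Gusb at 0 in both replicates. The pan-neuronal list, with medians of 5.15% and 3.34%, lay at the 98.8th and 99.5th percentiles, and with random lists not matched on gene length it no longer stood above them. The housekeeping list lost its place with the authors' pooled list, and with peaks of a −log10 q of at least 2, a limit added after the data were seen, the splicing, proteasome, H3K36 and protocadherin lists were the 4 that stood above. None of the 9 lists stood above the random lists when only peaks with a −log10 q of at least 5 were used, a limit that left 9428 peaks in replicate 1 and 476 in replicate 2. A list whose members mostly hold no covered base has a median of 0 and cannot be called above. With so few peaks, the loss of lists therefore does not show that their enrichment was weaker.

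The genes that write, remove or bind H3K36 methylation were themselves among the lists above the random ones, with 11 of 20 marked and medians of 14.9% and 11.7%. Setd2, which encodes the enzyme that trimethylates H3K36, had 14.8% ± 5.19 of its span covered (chromosome 9, 110532597 to 110618633 in mm10). Nsd1, which encodes an enzyme that adds the lower methylation states, had 18.9% ± 5.70 (chromosome 13, 55209782 to 55318325). The highest members were Kdm4a, a demethylase of H3K36, at 40.9% ± 4.00 and Brpf1, a reader protein, at 36.3% ± 3.35. Psip1 had 22.1% ± 10.03, but 45.7% of its covered bases lay where the neighbouring gene Snapc3 overlaps it. The DNA methyltransferase gene Dnmt3b had 0.264% ± 0.373, from replicate 1 alone, and Kdm8 held no covered base.

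By their medians, which could hardly be called below, lists of region-specific neuronal and progenitor genes lay within the range of random lists. None of their genes was marked. By the mean covered share, a measure added after the data were seen, the subpallial list lay below the random lists. Of the 18 pallial glutamatergic genes 7 held no covered base, Tbr1 among them, and the highest were Cux1 at 2.62% ± 0.769, Bcl11b at 2.48% ± 0.241 and Fezf2 at 2.22% ± 3.14, from replicate 1 alone. Among the 18 subpallial GABAergic genes, Gad2 and Gad1, which encode the enzymes that make GABA, had 4.81% ± 1.89 and 4.08% ± 3.12, Meis2 had 1.62% ± 1.04, and 14 held no covered base. For the radial glia and progenitor genes the highest values were Dbi at 8.37% ± 0.390, Ptn at 3.77% ± 1.02 and Vim at 2.80% ± 3.97 (replicate 1 alone), and Sox2 and Sox9 held none. The long neuronal adhesion genes were covered over small parts of their spans, with Auts2 highest at 1.42% ± 0.274, Magi2 at 0.320% ± 0.183, Nrxn1 at 0.239% ± 0.0708 and Lrp1b and Grid2 at 0. Of the synaptic genes, Dlg4, the gene of a postsynaptic scaffold protein, was marked at 11.5% ± 1.21, and Syngap1 averaged 12.0% ± 7.35 but passed in replicate 1 only, and Shank1 had 6.46% ± 2.70. The cell cycle list also lay within the random range, with medians of 5.20% and 2.15% at the 92.5th and 91.9th percentiles. Of its 16 genes 4 were marked, among them Cdk4 at 56.7% ± 0.338 (25.8% of its covered bases inside Tspan31). The replicative helicase genes Mcm7 at 23.7% ± 0.613 and Mcm4 at 17.4% ± 2.69 were also marked, while Ccnb1 and Aurkb held no covered base.

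Markers of the other cell types that a dissected forebrain could hold had few peaks, and the highest of them overlap other genes. Of all protein-coding genes, 53.7% held no covered base. The oligodendrocyte, microglia, choroid plexus and erythroid lists lay within the random lists by every measure used. Of the 12 oligodendrocyte lineage genes only Cnp was marked, at 27.8% ± 6.32, and 81.8% of its covered bases lay in the overlapping gene Dnajc7. Cx3cr1, the highest microglia gene at 4.92% ± 1.76, had all of its covered bases (100%) inside other protein-coding genes, and of those in Csf1r (2.63% ± 1.29) 66.6% lay in Hmgxb3. In the choroid plexus list, Kcnj13 had 5.58% ± 1.68, all of it inside Gigyf2, and Ttr held none. The astrocyte gene Gja1 had 1.36% ± 1.93, from replicate 1 alone. Fn1 was the only covered gene of the meningeal and mesenchymal list, at 1.96% ± 0.275, and Pdgfrb that of the endothelial and pericyte list, at 0.563% ± 0.795. The globin genes of the erythroid list held no covered base. In the imprinted list Nnat was marked at 39.1% ± 7.40, with all of its covered bases in the overlapping gene Blcap. Igf2r had 12.8% ± 5.71 and Peg3 10.7% ± 3.78, each above 10% in replicate 1 only, and of the list's 4 non-coding members Nespas, whose span overlaps the coding gene Gnas, had 19.6% ± 2.81, above 10% in both replicates, Meg3 had 4.37% ± 3.42, Kcnq1ot1 0.211% ± 0.298 and H19 had 0.

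No covered base was found in either replicate in the 39 Hox genes, the 14 liver genes, the 12 germline genes or the 68 histone genes. Of 1453 chemosensory receptor genes, 1450 held none, and Tas2r107, the highest, had 16.5% in replicate 1 and 0 in replicate 2. The striated muscle gene Ttn had 0.733% ± 0.129, and the other 13 genes of that list had none. Of the immediate early genes, Junb had 13.1% in replicate 1 and 0 in replicate 2, and Nr4a1 had 1.04% ± 0.293. A list's median could rarely, if at all, fall below the random lists by the rule used, since 53.7% of all protein-coding genes held no covered base. The lower limit of the random lists was above 0 only for the long neuronal adhesion genes, in replicate 1 (0.00683%). By the mean covered share, a measure added after the data were seen, 10 lists lay below the 2.5th percentile in both replicates: the subpallial, astrocyte, endothelial, meningeal, Hox, liver, muscle, germline, chemosensory and histone genes. By the share of marked members, a measure fixed beforehand, only the Hox and chemosensory lists did.

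**Figure D1:**
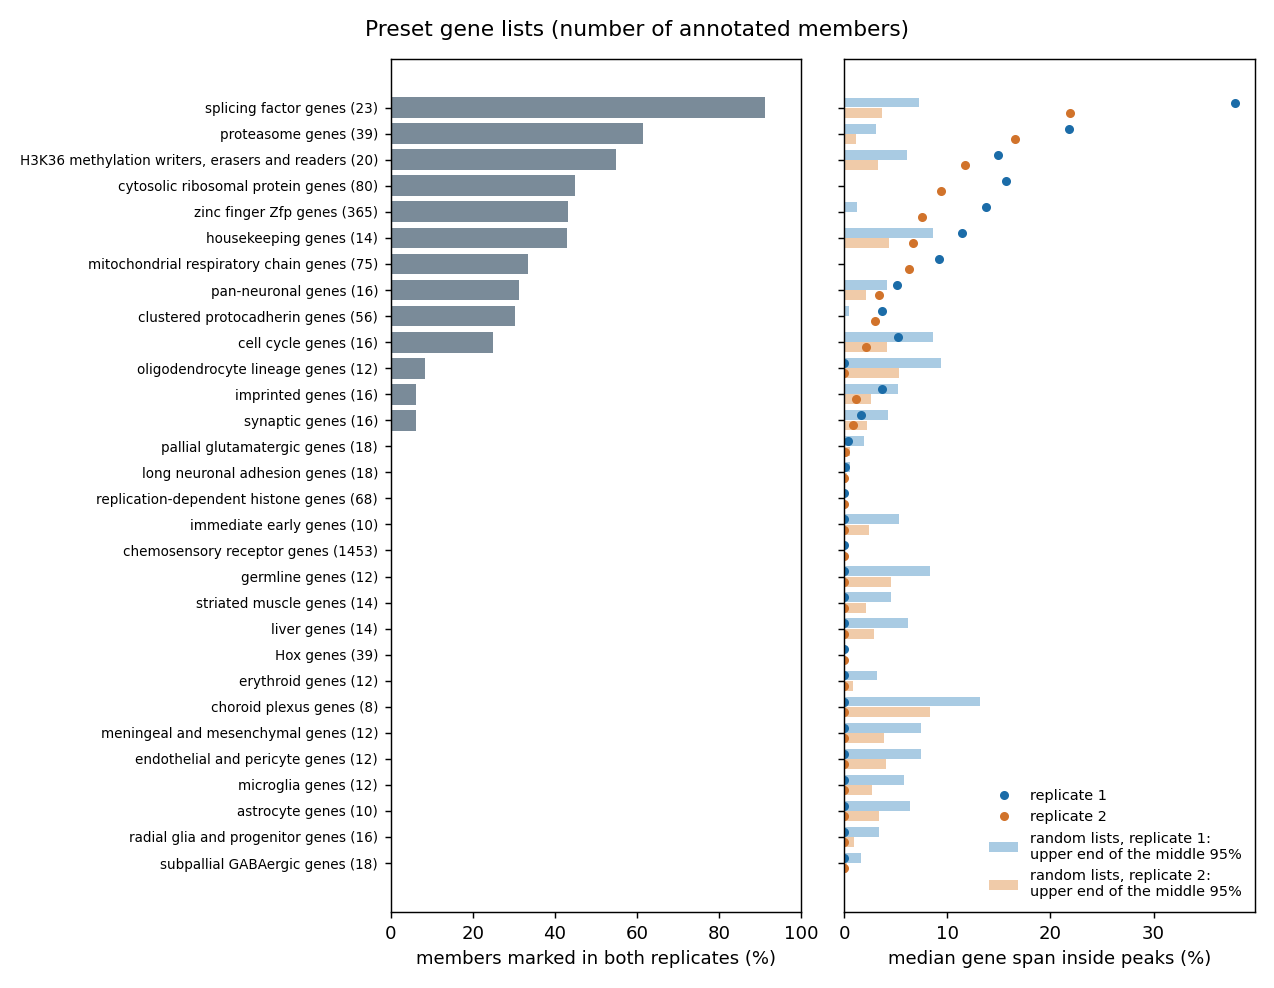
Preset gene lists, with the number of annotated members in brackets. The left panel shows the percentage of members marked in both replicates, and the right panel the median percentage of the gene span inside peaks in each replicate (points) over bars that reach up to the top of the middle 95% of 10000 length-matched random lists in the same replicate. Splicing factor genes were highest in both panels, with 91.3% of members marked.

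Zinc finger genes held many of the strongest and most completely covered sites, although 76 of the 365 genes of the Zfp list held no covered base. Of the 10 protein-coding genes of at least 5 kb with the highest covered share, 8 were Zfp genes (counting Zfp518b), led by Zfp110 at 81.6% ± 2.98 (chromosome 7, 12834761 to 12850577), Zfp606 at 80.8% ± 4.73, Zfp2 at 78.0% ± 4.40 and Zfp68 at 74.9% ± 6.10. Zfp90 had 70.98% ± 10.3, Zfp518b 70.3% ± 0.861, Zfp263 60.2% ± 1.85 and Zfp157 59.6% ± 11.9. The others were Ccdc177 at 70.4% ± 0.734 and Eif4g2, a translation initiation factor gene, at 64.7% ± 6.73. The peak with the highest fold in the authors' list of replicated peaks, 17.67, lay in Zfp68 (chromosome 5, 138604434 to 138608810) and overlapped its coding exons and untranslated region over 3388 of its 4377 bp. In the replicates' own lists the highest peak there had a fold of 14.5 and 14.4. Zfp157, Zfp37 and Zfp354c held further peaks among the 5 of highest fold, at 15.1, 14.9 and 14.6. The remaining peak of these 5, at 15.5 (chromosome 9, 124268519 to 124270079), overlapped no gene of the GENCODE annotation. The longest replicated peak, 10714 bp, lay in Zfp180, and a peak of 8512 bp spanned parts of Hjurp and Mroh2a. Zfp369, Srrm2 and Zfp110 held the next, of 6345, 6272 and 6175 bp. These folds are the authors' own value per peak.

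Across all 21938 protein-coding genes, 2876 (13.1%) were marked, and 11775 held no covered base in either replicate. Macf1, the gene of a cytoskeletal linker protein, had 51.2 kb inside peaks, 15.3% ± 3.64 of its span. Ubr4, a ubiquitin ligase gene, had 44.2 kb, 32.2% ± 5.35 of its span, with 14.7% of its covered bases inside the overlapping gene Emc1. The other 8 of the 10 genes with the most covered bases share at least 96.7% of them with other coding gene models. Pcdhga1, Pcdhga2, Pcdhga3 and Pcdhgb1 and the models Gm42416, Gm37013 and Gm37388 overlap one another on chromosome 18, and Gm20388 spans 73 other coding genes on chromosome 8, Tubb3 among them. Of the 2492 genes longer than 100 kb, 68 (2.73%) were marked, against 1398 of 6503 genes (21.5%) of 10 to 30 kb. A rule on the share of the span asks for more covered bases in a longer gene, so part of this contrast comes from the rule. With at least 2 kb covered in each replicate, at any gene length, 3611 genes passed. With peaks of a −log10 q of at least 5, 63 genes were marked. In the authors' list called on both replicates together the count was 4667, but there a gene has to pass in a single list, as in replicate 1 alone, where 4473 genes passed. With at least 25% of the span required it was 558.

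Coverage lay inside genes and rose along them. Protein-coding gene spans held 94.8% ± 0.343 of peak bases (n = 2), although they make up 38.2% of the assembled chromosomes. In 100 random circular shifts of the peaks within chromosomes that share reached 44.3% at most. Coding exons held 14.3% ± 1.43 of peak bases, 11.8 times their share of the genome, and introns 66.1% ± 1.24, 1.94 times their share. Windows of 1 kb on either side of transcription starts held 0.413% ± 0.0183, which is 0.273 times their share, and intergenic sequence held 4.25% ± 0.263. Over 13881 protein-coding genes of at least 5 kb that overlap no other coding gene, coverage was 0.377% ± 0.153 in the first of 10 equal bins of the gene body, 7.48% ± 2.12 in the ninth and 6.98% ± 2.06 in the last. The last 5 bins together had 2.47 ± 0.108 times the coverage of the first 5.

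Exon bases of protein-coding genes were covered at 8.91% ± 2.49 and intron bases at 2.13% ± 0.746, a ratio of 4.24 ± 0.313, above 1 in both replicates (4.02 and 4.46). Within marked genes alone the ratio was 1.62, and with peaks of a −log10 q of at least 5 it was 7.67. In 465 marked genes with no other coding gene within 10 kb, a set chosen after the data were seen, the kilobase before the start held no covered base in either replicate and the kilobase after the end had 19.7% ± 5.84. The fifth kilobase after the end had 1.60% ± 0.709.

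**Figure D2:**
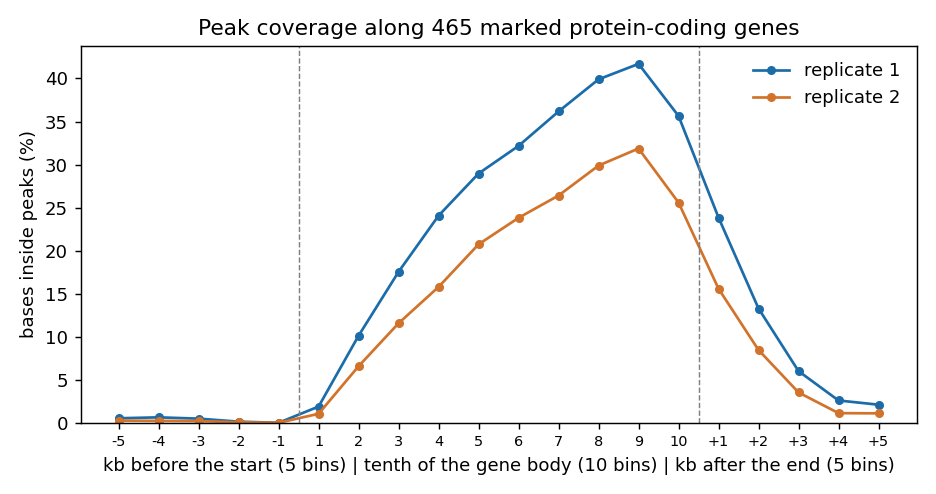
Percentage of bases inside peaks in each replicate along 465 marked protein-coding genes with no other coding gene within 10 kb: 5 bins of 1 kb before the start, 10 equal bins of the gene body and 5 bins of 1 kb after the end. Coverage is near 0 before the start, highest in the ninth bin of the body (41.7% and 31.9%) and falls over the kilobases after the end.

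A smaller part of gene bases lay inside peaks on the X chromosome than on any autosome. Of 948 protein-coding genes on the X, 9 (0.949%) were marked, against 2867 of 20807 (13.8%) on autosomes. The highest X gene was Ddx3x, an RNA helicase gene, at 24.04% ± 7.92, followed by Eif2s3x at 21.7% ± 1.39 and the histone demethylase gene Kdm5c at 21.6% ± 1.02. Amer1 had 20.8% ± 6.73 and Flna, which encodes an actin crosslinker, 13.4% ± 0.282. These X genes were named after their values were seen. Peaks covered 0.407% ± 0.149 of X gene bases and 2.87% ± 0.945 of autosomal gene bases, a ratio of 0.141 ± 0.00570 (n = 2), and the lowest autosome, chromosome 14, had 1.94% ± 0.737. Chromosome 11 had the highest value, 4.01% ± 1.33, and the Y chromosome held 8 peaks in replicate 1 and 2 in replicate 2. The X ratio was 0.0871 with peaks of a −log10 q of at least 5.

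**Figure D3:**
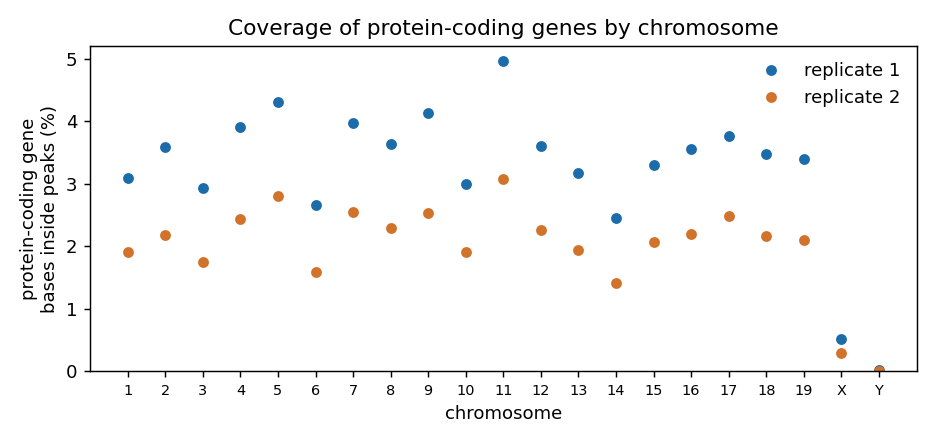
Percentage of protein-coding gene bases inside peaks on each chromosome in replicate 1 and replicate 2. The X lies at 0.513% and 0.302%, below every autosome in both replicates.

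Largely the same genes were covered in the replicates, and to a larger extent in replicate 1. Replicate 1 had 4473 marked genes and replicate 2 had 2996, of which 2876 were shared, while independent lists of these sizes would share 611. Across all genes the covered share correlated between the replicates with Spearman's rho of 0.906 and Pearson's r of 0.914. Genes are not independent replicates, so no p-value is given. Among genes of at least 5 kb, the largest differences towards replicate 1 were in Plscr3 (38.8% in replicate 1 and 0 in replicate 2), the splicing factor gene Srsf6 (54.7% and 19.04%) and the mitochondrial chaperone gene Hspa9 (55.0% and 23.6%), followed by Poldip2 and Zc3h10. Towards replicate 2 they were in Cox4i1, a respiratory chain gene (10.9% and 32.1%), Trmt2a (17.5% and 34.9%) and Plekho1 (19.8% and 35.1%), followed by Pabpn1 and Gm49776. All covered bases of Cox4i1, Trmt2a, Pabpn1 and Gm49776 lay in bases shared with other coding gene models. With 1 sample per side, these differences have no replicate check. With peaks of a −log10 q of at least 5, rho across genes was 0.291.

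The positions of peaks were shared between the replicates beyond random shifts of the peaks. Of replicate 1's peaks 34.5% (40807) overlapped a replicate 2 peak over at least 50% of either peak, and of replicate 2's peaks 55.9% (41925) overlapped one of replicate 1. The highest values in 100 random circular shifts were 1.72% and 2.72%. The lists had 12.3 Mb in common of 48.2 Mb in either, a Jaccard index of 0.255 against at most 0.00885 in the shifts. In the strongest of 10 equal groups by p, 68.6% of replicate 1 peaks and 82.6% of replicate 2 peaks were shared, and in the weakest 18.96% and 39.9%. Within 5694 non-overlapping genes of at least 5 kb with covered bases in both replicates, the lists shared 8.89 Mb, against at most 3.47 Mb when replicate 2 peaks were shifted at random inside each gene, a comparison added after the data were seen. Shifts along chromosomes move peaks out of genes. Shifts inside genes undo the rise along genes and the higher exon coverage that both lists have. Neither kind separates agreement of single peaks from these common features. Required over 50% of both peaks, sharing was 20.4% and 32.1%, and with peaks of a −log10 q of at least 5 it was 4.08% and 82.8% (Jaccard index 0.0773), from lists of very unequal length.

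**Figure D4:**
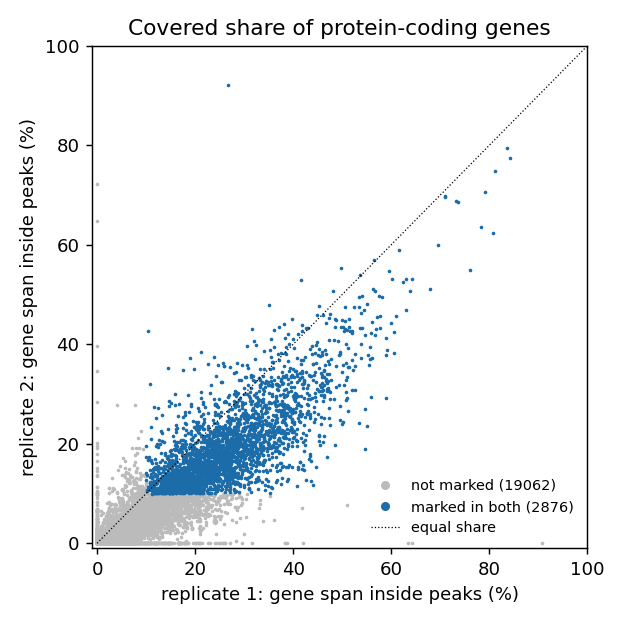
Percentage of each protein-coding gene's span inside peaks in replicate 1 (horizontal axis) and replicate 2 (vertical axis), one point per gene, with genes marked in both replicates in blue and the dotted line at equal shares. The 2876 marked genes lie mostly below the line, and 19062 genes were not marked.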

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

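In this part the test of the cell makeup of the pools was chosen after the result was seen. Outside the gene comparisons, which used assembled chromosomes, 12 peaks of replicate 1 and 7 peaks of replicate 2 lay on unplaced scaffolds. Both numbers pass 3, the upper limit that goes with a count of 0, as any list with a few such peaks would. The scaffold GL456216, placed on chromosome 4 without a position, held 4 of those of replicate 1 and 3 of those of replicate 2, with a highest fold of 4.54 and 3.44.

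Genes of the preset Zfp list held 62 of the 100 peaks of highest fold in the replicated list, although Zfp gene spans make up 1.05% of protein-coding gene bases. They held 18.8% of the 1000 peaks of highest fold and 2.45% of all replicated peaks on chromosomes. Sequence shared between gene copies, which would bring in reads from paralogs, is argued against for the 62 peaks. The median share of their 31-base words found elsewhere in the genome was 2.37%, and it was set beforehand that a median under 5% would speak against this cause (read length is not known). The other 38 of the 100 peaks had a lower median, 0.902%. The covered shares of the whole Zfp list were not tested in this way. With Zfp354c (1.51%) and the pseudogene Zfp939 (24.2%), which lie outside the list, the Zfp peaks numbered 64 and their median stayed at 2.37%. Long exons stay open. The Zfp median covered share stayed above 10000 random lists matched on the longest exon, at the 100th percentile in the lower replicate. Those lists were drawn from all protein-coding genes, and their upper limits were only 1.31% in replicate 1 and 0.326% in replicate 2. A list of mostly covered genes could thus pass with any exon length, and the fold of peaks was not matched on exon length. No biological explanation was tested, since the design has no second group, and GC content was not tested and stays open, as does the hypothesis that these genes carry the mark more densely than other transcribed genes.

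The X chromosome had 0.141 ± 0.00570 times the coverage of autosomes (n = 2). A larger share of silent genes on the X is argued against as the whole cause: among genes of ubiquitous lists, the 10 on the X, such as Hprt, Pgk1 and Rps4x, had a mean covered share of 1.19% and the 220 on autosomes 15.97%, a ratio of 0.0748 (0.102 in replicate 1 and 0.0353 in replicate 2; two-sided permutation p = 2e-05, the smallest that 100000 resamples can give), and 0 against 111 were marked. The X and autosomal genes were not matched on list or gene length, so the ratio also holds differences in list makeup. The splicing factor genes, with mean covered shares of 37.4% in replicate 1 and 24.3% in replicate 2, are all on autosomes. The ubiquitous list of lowest mean, the respiratory chain genes, had 12.2% and 8.74%. A cut of the whole fold to 0.5 was tested by comparing X bases in peaks of fold 3 or more with autosomal bases in peaks of fold 6 or more. This rests on reading the signal value as a linear ratio. X coverage came to 3.41 times the autosomal value, outside the range of 0.5 to 2 set beforehand, so such a cut would lose more than was lost. The test does not cover a cut to 0.5 of only the part of the fold above background, which an autosomal limit below 6 would match. Equal coverage was reached at an autosomal fold of 5.04 ± 0.226 in place of 3. A cut of that kind, or another smaller cut in fold, which 1 active X in each cell of a mixed-sex pool may bring, stays open. Effects of the authors' background model stay open too.

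Replicate 1 covered 37.4 Mb and replicate 2 covered 23.2 Mb. With equal peak numbers, 711 genes were marked in replicate 1 only and 386 in replicate 2 only, a ratio of 1.84 where it was 1597 to 120 before. This does not test the longer list as a source, since the peaks are alike in width and the cut alone brings the covered bases to 26.8 Mb against 23.2 Mb. A different cell makeup of the pools is not separated by the tables: the log2 ratio of covered share was higher by 0.31 in neuronal than in ubiquitous genes (two-sided permutation p = 0.0468, 37 and 166 genes), but by 0.00123 once genes of like covered share were compared (95% bootstrap interval -0.24 to 0.32). The longer list, depth and the further input file listed for replicate 1 cannot be told apart with these lists, and it is not known whether that file was used for replicate 1 alone.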

How the results depend on the processing

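The alternatives with a −log10 q of at least 2, the mean covered share of lists, the removal of read-through models and the count of bases in a single coding gene were chosen after the data were seen. The shared peaks, the Jaccard index and the share of peak bases in coding genes stayed beyond the highest shift under every alternative run for them. Over all comparisons 86 alternative values stayed within the limits set and 29 moved, with no ratio crossing 1. The cause of the moves was not tested. The limits were wide for some results, so the 86 do not mean like values. Sharing only had to pass the highest shift, so 4.08% of replicate 1 peaks at a −log10 q of at least 5, against 34.5%, counted as within. So did 4185 marked genes in the replicated list, against 2876. With 1 replicate left out, the position, exon to intron and X ratios stay within 1 SD by arithmetic. With a −log10 q of at least 5, the ratio of last to first bins was 3.66, exon to intron 7.67, X to autosome 0.0871, marked genes 63, rho across genes 0.291 and lists above random ones 0. With at least 2, these were 2.78, 5.04, 0.0999, 421, 0.659 and 4, and the pan-neuronal, ribosomal, respiratory chain, Zfp and housekeeping lists were lost. A list with a median of 0 cannot be called above, so lists lost at these 2 limits may be lost by the rule on medians. The position ratio was 2.18 in genes of at least 20 kb and 2.25 in marked genes, where exon to intron was 1.62. Joining peaks within 1 kb gave 3.86 for exon to intron and 0.123 for X to autosome. The X ratio was 0.135 with equal peak numbers, 0.102 in the replicated list, 0.109 in the pooled list and 0.0956 over whole chromosomes. Marked genes numbered 4667 in the pooled list, which also lost the housekeeping list, 4597 at 5% coverage, 558 at 25%, and 2996 to 4473 with 1 replicate left out, as in these and in the pooled list a single list must pass. Rho was 0.895 with a fold of at least 3 and 0.926 in genes of at least 5 kb. Lists below random ones numbered 2 by the share of marked members (Hox and chemosensory) and 10 by the mean covered share. With bases in a single coding gene only, the protocadherin list was lost. For single lists 391 values kept their call, 17 lost it and 12 gained it, and for the 117 named genes 741 values stayed within 1 SD, 144 were higher and 168 lower. Part of these outcomes was fixed in advance. With 1 replicate left out, a named gene lies within 1 SD by arithmetic, and a list above in both replicates stays above. Lists with a median of 0 could rarely, if at all, be called below by it. The counts of unchanged values thus overstate stability. No paired analysis was possible because there is only 1 group. Unknown depth limits what an absent peak means.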

Other observations

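Few non-coding genes carried the mark outside coding genes. Of 3381 long non-coding genes of at least 5 kb that overlap no protein-coding gene, 8 (0.237%) were marked. The highest were Snhg17, a host gene of small nucleolar RNAs, with 31.8% ± 3.94 (SD, n = 2) of its span inside peaks (chromosome 2, 158353700 to 158361580), 5430416N02Rik with 24.3% ± 2.25 and A830082N09Rik with 22.4% ± 1.34. Among the 100 replicated peaks of highest fold, 2 lay in the non-coding gene Tug1 on chromosome 11, of fold 12.8 (3643802 to 3645865) and 9.12 (3640452 to 3643501). All of these were named after their values were seen.

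Of 79864 replicated peaks on chromosomes, 2864 (3.59%) lay outside every GENCODE gene, and 407 of those (14.2%) lay inside a RefSeq gene. The strongest, of fold 15.5 (chromosome 9, 124268519 to 124270079), covered an exon of the RefSeq model Gm39469 from 124268543 to 124269936. A peak of fold 7.51 on chromosome 5 (110130017 to 110130992) lay in the RefSeq span of Zfp605. The peak of fold 7.65 on chromosome 7 (12496485 to 12497993) begins beyond the annotated end of Zfp606 at 12496235.

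The authors' p values came in steps. In replicate 2, 13.0% of peaks had the same −log10 p of 3.65 and the 10 commonest values held 55.0% of peaks. In replicate 1 the commonest value, 4.60, held 6.69% and the 10 commonest 39.2%. Over 43919 replicated peaks with a peak in both replicates, the fold correlated between the replicates with Spearman's rho of 0.232 and Pearson's r of 0.352 across peaks, which are not independent replicates.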
